A study of Mus musculus with 21 samples.

How the data were processed

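RNA was measured in 21 libraries of the mouse embryonic stem cell line 2TS22C. Per the labels' protocols, total RNA was taken with Trizol, mRNA was selected on oligo(dT) beads, and complementary DNA was made from fragments with random hexamers. Strand use in the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. The values came as a single deposited table of 16443 genes with identifiers and symbols. Per the submitters' processing notes, RSEM and Bowtie2 2.0 were used with the mm10 genome. The deposited values are treated as a score: whole numbers that the authors had normalized between libraries and rounded, because the sorted values of any 2 libraries differ by at most 3 and 66.3% of the ranks hold an identical value in every library. The normalization software is not given in the sources used here. Every gene exceeds 20 in at least 2 libraries, which points to a filter applied before deposit. Because the totals were made equal, read depth is unknown and no interval that needs it was computed.

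Columns were assigned by name: 16 matched 1 sample each, and 5 (p21 and p31) matched a group only, so they serve as replicates with no number of their own. All columns were used. Groups come from the labels, and 8 groups were formed from 4 lines and 2 media. Coordinates are those of the GENCODE M21 annotation of GRCm38 (mm10), in which all 16443 identifiers have a location and 16364 symbols are identical. GC content was taken from the longest transcript.

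The main test was limma 3.58.1 in R 4.3.3 with an intensity trend and robust variance moderation, on log2(value + 1). A log2 change on this scale understates the change of low genes. A single model with a term for each group and a term for the wave took in all 21 libraries, leaving 12 residual degrees of freedom. The wave term in SL rests on the 2i libraries. A gene changed when its Benjamini-Hochberg adjusted p over the 16443 genes was under 0.05. The filter (a value of at least 1 in at least 2 libraries) left out 0 genes. A test for counts had been planned, with limma on log2 values as its written fallback for normalized tables. The fallback was used because the values are not counts. The groups, comparisons, tests, gene lists and rule for named genes, and most alternatives, were fixed before the data were examined. P-values from limma are two-sided.

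The comparisons were SOX2, FNV and miniSOX against NTC, FNV and miniSOX against SOX2, each within a medium, 2i against SL in NTC, and the difference between media of FNV against SOX2. Named genes were Sox2 and Sox17, the 6 largest increases and 6 largest decreases among changed genes with a mean of at least 5 in the higher group and no overlap between libraries (predicted genes left out), up to 4 genes of each list that passed, and for the interaction the 6 with the smallest adjusted p. Of the 132 places for largest changes, 97 went to step genes. The text names a part of the genes so chosen, mainly those that are not step genes, and this part was chosen after their values were seen. The result of 1 named gene is not reported here.

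The 17 gene lists were naive, general, and formative and primed pluripotency, trophectoderm, primitive and visceral endoderm, primitive streak and mesoderm, neuroectoderm, 2-cell-like, ERK pathway targets, Wnt and beta-catenin targets, Sox family, germline, p53 targets, interferon response, integrated stress response, fibroblast, and imprinted genes. Each was tested with camera of limma at a preset correlation of 0.01, adjusted over all lists and comparisons together. Of these 204 tests 52 passed, and 0 held with an estimated correlation. Of the 52, 48 also passed fry, which asks whether a list's genes move one way and does not compare them with other genes. In each list that passed, the median and the mean of its members had the sign of the test. Beside each count over all genes stands the count adjusted over the list alone.

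In simulated data with 200 of 16443 genes changed, FNV against SOX2 in 2i recovered 61.2% of 67 genes at 1.5-fold, 89.6% of 67 at 2-fold and 100% of 66 at 4-fold, and in SL 28.4%, 68.7% and 97%, with 8 other genes called in each. Real libraries vary unequally, so these may differ. Alternatives covered the pseudocount (0.1 and 10), a filter at a mean of 50, a repeated quantile normalization, the wave term, single waves, first-wave replicates averaged, the replicate number as a block, the groups in the model, the list correlation, and leaving out each library in turn. Chosen after seeing the data were centring on the median log ratio, the p21 and p31 prefix as a term, the pseudocount of 10, the filter at 50 and the fit without step genes. So were, for single genes, the single waves, the replicate block and leaving out libraries (the last also for list members), and all fits that compare miniSOX with FNV or miniSOX between media. Figures were drawn with matplotlib 3.10.9.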

Results

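The data are poly(A) RNA sequencing profiles of 2TS22C, a mouse embryonic stem cell line. According to the labels, endogenous SOX2 was silenced and the cells were carried by a lentiviral rescue factor under doxycycline treatment. Rescue factors were SOX2 itself, SOX17FNV (FNV in what follows), an engineered form of the endoderm factor SOX17, and miniSOX, which the labels give by name only. Untransduced 2TS22C cells (NTC), whose labels list no doxycycline, were the control. Cells grew in serum and LIF (SL) or in the same medium with 2i, which blocks MEK and GSK3. The 21 libraries fall into 8 groups: in 2i, 3 NTC, 4 SOX2, 4 FNV and 2 miniSOX libraries, and in SL 2 libraries of each. They came in 2 deposited sets told apart by their titles and organism labels, here called waves. The first wave holds 12 libraries (replicates 1 and 2 of NTC, SOX2 and FNV in both media), and the second wave holds the 5 libraries called p21 or p31 (all in 2i) and every miniSOX library.

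The deposited values cover 16443 genes. All libraries hold nearly the same set of values, with totals from 14044316 to 14047262 and a median of 214 in each, so the sequencing depth of a library is unknown and no counting interval is given. Among genes between 500 and 1500, the SD of the log2 difference between replicates 1 and 2 was 0.097 in NTC, 0.109 in SOX2, 0.129 in FNV and 0.117 in miniSOX cells in 2i, and 0.185, 0.26, 0.233 and 0.104 in SL. Between the p21 and p31 libraries it was 0.27 in SOX2 and 0.406 in FNV cells. No label says whether replicates 1 and 2 came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of 2142 genes listed at 0 in some library, 691 had no value between 0 and 20 (here called step genes), among them Kctd12b, Cntn3 and Cdh19, so a 0 in the deposited values does not show that a transcript was missing.

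**Figure D1:**
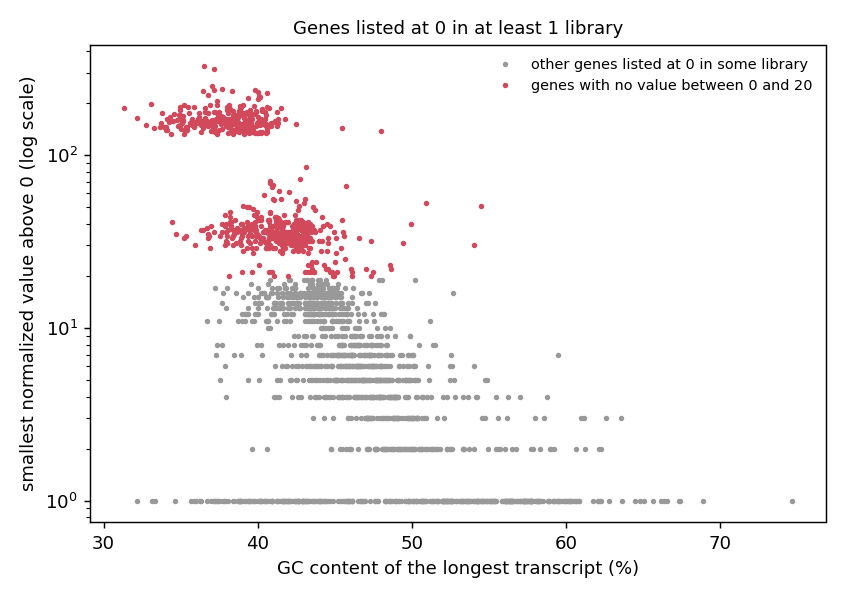
Smallest normalized value above 0 (log axis) against the GC content of the longest transcript in percent, with 1 point for each of the 2142 genes listed at 0 in some library. The 691 step genes (red) have a median GC content of 40.2 percent, and the 15752 genes that are not step genes have one of 47.9 percent.

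Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461, plus strand), the silenced factor, stood at 1310, 1362 and 2697 in the NTC libraries in 2i and at 533 and 843 in SL. In SOX2-rescued cells it was 1509, 1251, 939 and 947 in 2i and 1389 and 921 in SL, where reads from the rescue factor and from the endogenous gene are not separated. In FNV cells it was 35, 36, 43 and 19 in 2i and 49 and 33 in SL, and in miniSOX cells 47 and 60 and 48 and 55. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354, minus strand) was 3160, 3301, 1792 and 2659 in FNV cells in 2i and 13693 and 30391 in SL. MiniSOX cells gave 1813 and 1953 in 2i and 4179 and 4138 in SL. In the other groups Sox17 lay between 0 and 6. Against NTC, Sox2 fell in FNV cells in 2i (log2 change -5.67 ± 0.32 (SE), adjusted p = 8.7e-09) and in SL (log2 change -4.03 ± 0.41 (SE), adjusted p = 7.37e-06), and in miniSOX cells in 2i (log2 change -4.92 ± 0.41 (SE), adjusted p = 1.27e-06) and in SL (log2 change -3.62 ± 0.48 (SE), adjusted p = 0.00016). Without NTC p31, the log2 change went from -4.92 to -4.21 for Sox2 in miniSOX cells in 2i. SOX2-rescued cells did not pass against NTC in Sox2 by the test, in 2i (log2 change -0.56 ± 0.32 (SE), adjusted p = 0.211) or in SL (log2 change 0.75 ± 0.41 (SE), adjusted p = 0.238).

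**Figure D2:**
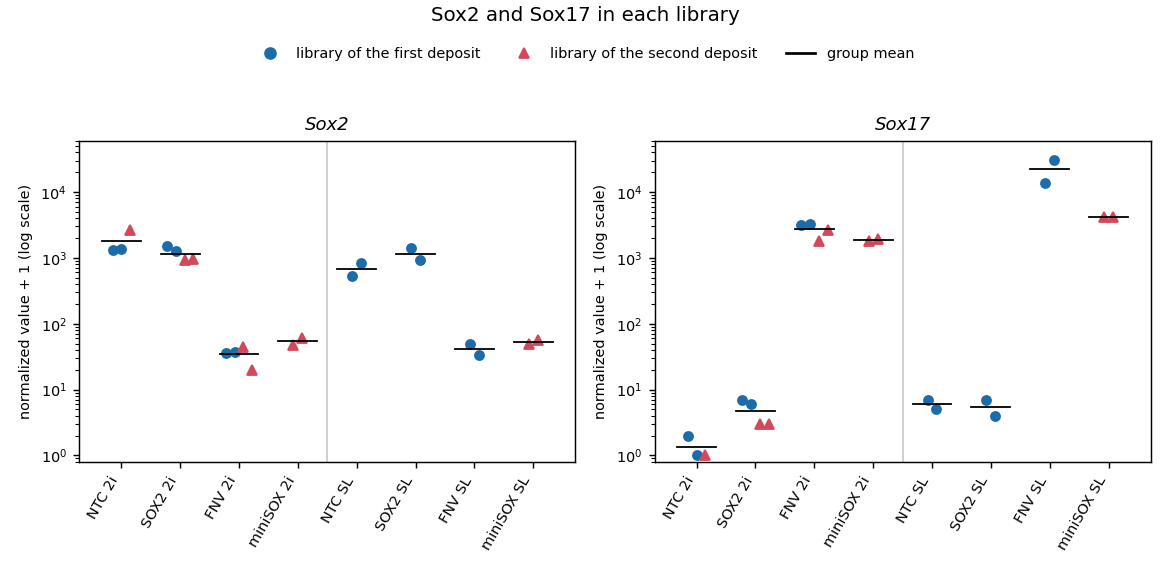
Normalized values of Sox2 and Sox17 plus 1 on a log axis, with 1 point per library by group and a line at each group mean. Sox2 lay between 19 and 60 in FNV and miniSOX libraries and at 533 or above in all others, and Sox17 lay at 1792 or above in FNV and miniSOX libraries and at 6 or below in all others.

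Untransduced cells were compared between media to give the background on which the rescue lines were set. In 2i, the naive pluripotency genes Klf4 (2480 ± 433 against 318 ± 0.707 in SL; SD, n = 3 and 2), Prdm14 (403 ± 60.3 against 91 ± 0) and Jam2 (2975 ± 1104 against 323 ± 0.707) were higher. Wnt pathway targets, which GSK3 inhibition activates, were also higher: Axin2, a feedback inhibitor of the pathway, was 589 ± 327 against 41.5 ± 9.19, Cdx1 141 ± 11 against 1.5 ± 0.707 and Tnfrsf19 692 ± 97.1 against 62.5 ± 7.78. Keratins of simple epithelia were lower in 2i, with Krt7 at 10 ± 4 against 499 ± 91.9, Krt8 at 565 ± 341 against 4892 ± 226 and Krt19 at 38.7 ± 16.9 against 1641 ± 84.1, as was the FGF receptor Fgfr2 at 49.7 ± 40.1 against 483 ± 2.83. The MEK and ERK feedback phosphatase Dusp4 (19 ± 4.58 against 861 ± 12.7) and Ier3 (76.3 ± 9.29 against 394 ± 36.8) were lower, while the cyclin Ccnd1 moved the other way (log2 change 5.04 ± 0.20 (SE), adjusted p = 5.15e-10).

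In this comparison 4053 genes changed, 1953 higher and 2100 lower, 1756 of them by at least 2-fold. For the naive pluripotency list, 11 of 18 measured members rose, 1 fell and 6 did not pass. 12 higher and 1 lower passed when adjusted over the list alone, and the list test gave adjusted p = 4.28e-06 (0.243 with an estimated correlation). In the formative and primed list, with Otx2 at 133 ± 10.3 against 432 ± 32.5, Pou3f1 at 3.33 ± 4.04 against 111 ± 66.5 and the DNA methylation cofactor Dnmt3l at 947 ± 476 against 4133 ± 64.3, 2 were higher and 9 were lower, while 6 of 17 did not pass. As a list it had adjusted p = 0.00551 (0.174 with an estimated correlation), and 3 higher and 10 lower passed when adjusted over the list alone. The trophectoderm list's 25 measured members divided into 2 higher, 14 lower and 9 not passing. With an adjusted p = 8.31e-06 (0.174 with an estimated correlation) the list passed, and 2 higher and 15 lower passed when adjusted over the list alone. For ERK pathway targets, 1 of 17 measured members rose, 9 fell (3 without NTC replicate 1 in SL, 5 without NTC replicate 2 in SL) and 7 did not pass. 1 higher and 10 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0152 (0.29 with an estimated correlation). Wnt and beta-catenin targets gave the opposite direction, in that 8 were higher and 1 was lower, while 6 of 15 did not pass. Its list test had adjusted p = 0.000534 (0.229 with an estimated correlation), and 8 higher and 1 lower passed when adjusted over the list alone. The interferon list, in which the membrane tether Bst2 was 246 ± 81.2 against 3421 ± 369, fell too: 0 were higher and 7 were lower (4 without NTC replicate 2 in SL), while 7 of 14 did not pass. The set gave adjusted p = 0.00364 (0.243 with an estimated correlation), and 1 higher and 10 lower passed when adjusted over the list alone. In the fibroblast list, kept as a marker of feeder or other cells, Col1a1 was 4 ± 2.65 against 48.5 ± 9.19, Acta2 3.67 ± 4.04 against 109 ± 8.49 and Tagln 5 ± 0 against 48.5 ± 2.12 (Tagln did not pass at a pseudocount of 0.1), and 0 of 14 measured members rose, 8 fell (5 without NTC replicate 1 or 2 in SL) and 6 did not pass. 0 higher and 8 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0113 (0.243 with an estimated correlation). Of integrated stress response genes, 5 were higher (1 without NTC replicate 1 in SL, 13 without NTC p31) and 0 were lower, while 17 of 22 did not pass. In the list test they had adjusted p = 0.0466 (0.68 with an estimated correlation), and 5 higher and 0 lower passed when adjusted over the list alone, but that list did not pass with no wave term. The count of changed genes rests on both SL libraries, being 2106 without replicate 1 and 2664 without replicate 2 of NTC in SL, and it was 2680 with no wave term and 789 with first-wave replicates averaged (1 library in SL). Without NTC replicate 1 in SL, the log2 change went from -5.18 to -5.82 for Pou3f1, without NTC replicate 2 in SL from -5.18 to -4.53 for Pou3f1, without NTC replicate 1 in 2i from -5.05 to -4.02 for Acta2, and without NTC p31 from -5.05 to -5.78 for Acta2.

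SOX2-rescued cells in 2i were compared with NTC to ask what the rescue with the native factor left different. ERK feedback genes were lower in the rescued line, with Spred1 at 707 ± 156 against 1022 ± 212 (SD, n = 4 and 3) and the phosphatase Dusp5 at 12 ± 2.94 against 45 ± 18.2. Wnt pathway genes were lower as well: the transcription factor Lef1 was 17.3 ± 4.11 against 139.7 ± 127 and Notum, a secreted Wnt inhibitor, was 43.3 ± 11.3 against 178 ± 162, with 286 and 365 in the p31 library of NTC. Without NTC p31, the log2 change went from -2.71 to -1.95 for Lef1 and from -1.82 to -1.19 for Notum. Among imprinted genes, the noncoding Mirg of the Dlk1 and Meg3 region was 115 ± 25.9 against 402 ± 62.5 and Usp29 199 ± 17.7 against 395 ± 223. The largest increases included Megf11, at 586, 595, 82 and 57 in the SOX2 and 20, 16 and 2 in the NTC libraries (log2 change 4.71 ± 0.33 (SE), adjusted p = 3.24e-07).

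In all, 4718 genes changed, 2374 higher and 2344 lower, 1458 of them by at least 2-fold. Within the first-wave libraries 5899 genes changed, and within the second wave, where NTC has 1 library, 1529. For ERK pathway targets, 0 of 17 measured members rose, 9 fell (5 without NTC p31) and 8 did not pass. 0 higher and 11 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.00212 (0.243 with an estimated correlation). Wnt and beta-catenin targets showed the same direction: 0 were higher and 5 were lower, while 10 of 15 did not pass. Over the list, camera gave adjusted p = 0.0135 (0.269 with an estimated correlation), and 0 higher and 6 lower passed when adjusted over the list alone. Axin2 in that list (229.8 ± 203 against 589 ± 327) did not pass with no wave term (log2 change -1.81 in place of -2.13). The imprinted list's 16 measured members divided into 0 higher, 7 lower (4 without NTC p31) and 9 not passing. By its list test, at adjusted p = 0.00795 (0.243 with an estimated correlation) the list passed, and 2 higher and 10 lower passed when adjusted over the list alone. The trophectoderm list did not pass: 2 were higher and 11 were lower, while 12 of 25 did not pass. For the list there was adjusted p = 0.098 (0.455 with an estimated correlation), and 3 higher and 11 lower passed when adjusted over the list alone. Nor did the fibroblast list, a marker of feeder or other cells: 5 were higher and 1 was lower, while 8 of 14 did not pass. As a list it had adjusted p = 0.237 (0.498 with an estimated correlation), and 5 higher and 1 lower passed when adjusted over the list alone. With no wave term 2947 genes changed, and 1694 with first-wave replicates averaged. The contrast also holds the doxycycline treatment and the viral transduction, which NTC cells lack.

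FNV cells in 2i were compared with NTC to describe cells carried by the engineered SOX17. Extraembryonic endoderm genes were higher in FNV cells: the endocytic adaptor Dab2 was 4505 ± 552 against 294 ± 90.4 (SD, n = 4 and 3), the endoderm transcription factor Gata6 328 ± 75 against 37.3 ± 33.5, and the matrix genes Nid1 and Sparc 7869.5 ± 876 against 2613 ± 748 and 3969.5 ± 479.7 against 1738 ± 86.4. Trophectoderm genes rose with them, among them Wnt7b at 234 ± 115 against 11.7 ± 8.14, the transcription factor Gata3 at 114 ± 37.7 against 13 ± 14 and the galectin Lgals3 at 296 ± 65.8 against 62.3 ± 37.9, whereas the T-box factor Eomes fell (log2 change -2.34 ± 0.29 (SE), adjusted p = 1.86e-05). The largest decreases were Kctd12b (ENSMUSG00000041633, chromosome X, 153685154 to 153696391, minus strand), listed at 0 in all 4 FNV libraries and at 554, 577 and 861 in NTC, the axon guidance ligand Ntn1 (5.75 ± 4.79 against 1379 ± 472), the semaphorin receptor Nrp2 (4.75 ± 2.63 against 1149 ± 394) and the receptor Notch4 (1.25 ± 1.5 against 402 ± 136). Without NTC p31, the log2 change went from 4.26 to 5.08 for Wnt7b and from 2.58 to 1.85 for Lgals3. Nid1 was also high in the other rescued lines in 2i, at 9102, 9102, 8024 and 9102 in SOX2 and 6869 in both miniSOX libraries. Sparc was 2818, 2932, 3208 and 2954 in SOX2 libraries in 2i, between NTC and FNV.

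Here 6529 genes changed, 3233 higher and 3296 lower, 2571 of them by at least 2-fold. The count was 6980 within the first wave 2911 within the second, where NTC has 1 library, and 3985 with first-wave replicates averaged. In the primitive and visceral endoderm list, 10 of 21 measured members rose, 4 fell and 7 did not pass. 12 higher and 4 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0219 (0.229 with an estimated correlation). In the trophectoderm list, 11 were higher and 2 were lower, while 12 of 25 did not pass. The members together had adjusted p = 0.0201 (0.328 with an estimated correlation), and 11 higher and 3 lower passed when adjusted over the list alone. The list of 2-cell-like genes, many of them members of families of near-identical copies whose reads cannot be assigned with certainty, passed toward higher values: 11 were higher (5 without NTC replicate 1, 6 without NTC replicate 2 or FNV replicate 2, 7 without FNV replicate 1) and 0 were lower, while 8 of 19 did not pass. Its list test had adjusted p = 0.00303 (0.492 with an estimated correlation), and 11 higher and 0 lower passed when adjusted over the list alone. Its members Sp110 (93 ± 40.7 against 21.7 ± 11) and Tmem92 (30 ± 10.4 against 6.67 ± 2.08) did not pass within the second wave alone (log2 change 1.83 in place of 2.06 and 1.42 in place of 2.00), and Sp110 reached 154 in the p21 library of FNV against 72 to 74 in the other 3. For ERK pathway targets, with Spred1 at 329.5 ± 28.7 against 1022 ± 212 and Spry4 at 8.75 ± 4.27 against 78.7 ± 60, 2 of 17 measured members rose, 10 fell and 5 did not pass. 2 higher and 10 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.00299 (0.243 with an estimated correlation). The ETS factor Etv4 stood at 22, 18, 15 and 129 in FNV and 1025, 1028 and 1379 in NTC libraries. Without FNV p31, the log2 change went from -5.30 to -5.89 for Etv4, and without NTC p31 from -2.99 to -2.33 for Spry4. The Sox family list did not pass as a whole, and it holds Sox17 and Sox2, the introduced and the silenced gene, whose changes in opposite directions follow from the construction of the line. Of its genes 1 was higher and 6 were lower, while 2 of 9 did not pass. Camera gave adjusted p = 0.111 (0.319 with an estimated correlation), and 1 higher and 6 lower passed when adjusted over the list alone. Nor did the fibroblast list pass, kept as a marker of feeder or other cells, with a median log2 change of 1.12: 7 were higher and 1 was lower, while 6 of 14 did not pass. In the list test they had adjusted p = 0.108 (0.407 with an estimated correlation), and 8 higher and 1 lower passed when adjusted over the list alone. This contrast, like the others against NTC, includes doxycycline and transduction.

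FNV and SOX2 cells, both transduced and treated with doxycycline, were compared in 2i to set the engineered factor against the native one. Simple-epithelium keratins were higher in FNV cells, Krt8 at 3176 ± 549.5 against 331 ± 216 (SD, n = 4 in both) and Krt18 at 2212 ± 749 against 103 ± 56.9, together with Lgals3 (296 ± 65.8 against 23 ± 6.38) and Wnt7b (234 ± 115 against 7 ± 2.58). Dab2 (4505 ± 552 against 868 ± 398), Gata6 (328 ± 75 against 64 ± 22.6) and the endocytic receptor Lrp2 (3981 ± 1018 against 1122 ± 522) were higher too. Of the naive pluripotency genes, the nuclear receptor Nr0b1 fell to 5 ± 4.97 from 231 ± 82.3, Tcl1 to 41 ± 43.2 from 812 ± 111 and Prdm14 to 237 ± 17.7 from 438 ± 44, while Dppa3, a maternal factor, rose (log2 change 2.50 ± 0.22 (SE), adjusted p = 2.12e-06). The trophectoderm determinant Cdx2 was 245, 235, 217 and 452 in the FNV and 0, 0, 27 and 40 in the SOX2 libraries, the highest FNV value coming from the p31 library (log2 change 5.56 ± 0.79 (SE), adjusted p = 0.000138). In NTC cells in 2i Cdx2 was 15 and 12 in replicates 1 and 2 and 519 in p31, above every FNV library. Without FNV replicate 1, the log2 change went from -5.74 to -5.08 for Nr0b1, without FNV p31 from -4.94 to -5.60 for Tcl1, and without FNV p21 from 5.56 to 6.33 for Cdx2.

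Between these lines 4150 genes changed, 2031 higher and 2119 lower, 1416 of them by at least 2-fold. The first wave alone gave 5605 and the second wave alone 837. In the trophectoderm list, 13 of 25 measured members rose, 2 fell and 10 did not pass. 13 higher and 2 lower passed when adjusted over the list alone, and the list test gave adjusted p = 1e-05 (0.174 with an estimated correlation). The primitive and visceral endoderm list's 21 measured members divided into 8 higher, 2 lower and 11 not passing. With an adjusted p = 0.027 (0.243 with an estimated correlation) the list passed, and 11 higher and 2 lower passed when adjusted over the list alone. Plat, in that list, was 168 in the p31 library of FNV against 301 to 325 in the other 3 and 76.3 ± 21.9 in SOX2 cells. For the naive list, 1 was higher and 10 were lower, while 7 of 18 did not pass. The list test had adjusted p = 0.0154 (0.443 with an estimated correlation), and 2 higher and 10 lower passed when adjusted over the list alone. For 2-cell-like genes, 4 of 19 measured members rose (1 without FNV replicate 1 or 2 or SOX2 p31, 2 without FNV p21), 0 fell and 15 did not pass. 4 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.00405 (0.498 with an estimated correlation). Kctd12b was listed at 0 in the FNV libraries and at 316, 193, 401 and 428 in SOX2, and Ntn1 (5.75 ± 4.79 against 622 ± 93.5) and Notch4 (1.25 ± 1.5 against 189 ± 35.8) were again among the largest decreases. The long noncoding H19 (9532 ± 6809 against 439.8 ± 725) was among the largest increases but did not pass within the second wave alone (log2 change 4.66 in place of 5.79). Without SOX2 p21, the log2 change went from 5.79 to 6.71 for H19. With no wave term 2695 genes changed, and 1545 with first-wave replicates averaged.

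MiniSOX cells in 2i, set against NTC, had lower ERK targets: Spred1 was 358 ± 1.41 against 1022 ± 212 (SD, n = 2 and 3), Etv4 53.5 ± 10.6 against 1144 ± 204 and Spry4 5 ± 1.41 against 78.7 ± 60. Kctd12b was listed at 0 in both miniSOX libraries, Ntn1 was 9 in both against 1379 ± 472, and the lactate transporter Slc16a3 fell to 12 ± 5.66 from 2222 ± 1099.7. Cdh19, a cadherin, was listed at 0 in the 3 NTC libraries and at 230 and 224 in miniSOX. Collagen genes went both ways, with Col5a1 up (210 ± 1.41 against 27.7 ± 6.35), Col1a1 up at a low level (15.5 ± 3.54 against 4 ± 2.65) and Col1a2 down (3.5 ± 0.707 against 35.7 ± 3.79). Without NTC p31, the log2 change went from -7.45 to -8.57 for Slc16a3 and from -3.77 to -2.89 for Spry4 and from 2.31 to 1.59 for Col1a1.

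The test called 4561 genes changed, 2347 higher and 2214 lower, 2147 of them by at least 2-fold. Of the wave 2 libraries alone, with 1 NTC library, it called 2837, and no first-wave value exists because miniSOX is in the second wave only. For ERK pathway targets, 0 were higher and 10 were lower, while 7 of 17 did not pass. As a list it had adjusted p = 0.000364 (0.229 with an estimated correlation), and 0 higher and 10 lower passed when adjusted over the list alone. The fibroblast list's 14 measured members divided into 7 higher (4 without miniSOX replicate 1 or 2), 1 lower and 6 not passing. At an adjusted p = 0.0351 (0.269 with an estimated correlation) the list passed, and 8 higher and 2 lower passed when adjusted over the list alone. Of 2-cell-like genes, 2 of 19 measured members rose (1 without miniSOX replicate 1 or 2, 12 without NTC p31), 0 fell and 17 did not pass. 2 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0184 (0.561 with an estimated correlation). Gm8300 in that list was 656 ± 12.7 against 416 ± 29.1 and did not pass within the second wave alone (log2 change 0.55 in place of 0.68). The count was 2842 without replicate 1 and 2712 without replicate 2 of miniSOX in 2i, 2772 with first-wave replicates averaged and 6947 with only the compared groups in the model.

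Against SOX2 cells in 2i, miniSOX cells showed higher Lgals3 (262 ± 58.7 against 23 ± 6.38; SD, n = 2 and 4), Krt18 (727 ± 15.6 against 103 ± 56.9) and Wnt7b (82 ± 24 against 7 ± 2.58). The neuronal tubulin Tubb3 fell to 17 ± 1.41 from 359.5 ± 209.8, and Spred1 to 358 ± 1.41 from 707 ± 156. Ntn1 fell to 9 in both libraries from 622 ± 93.5 (log2 change -6.45 ± 0.37 (SE), adjusted p = 7.56e-08), and Kctd12b was listed at 0 in both. Between these lines in 2i, 2449 genes changed, 1204 higher and 1245 lower, 987 of them by at least 2-fold. The second wave alone gave 1079. Among trophectoderm genes, 8 were higher (5 without miniSOX replicate 1 or 2) and 1 was lower, while 16 of 25 did not pass. Its list test had adjusted p = 0.0184 (0.319 with an estimated correlation), and 10 higher and 2 lower passed when adjusted over the list alone. The neuroectoderm list's 11 measured members divided into 0 higher, 4 lower (2 without miniSOX replicate 1 or 2) and 7 not passing. At an adjusted p = 0.0255 (0.269 with an estimated correlation) the list passed, and 0 higher and 4 lower passed when adjusted over the list alone, but not with no wave term. For ERK pathway targets, 1 of 17 measured members rose, 5 fell (3 without miniSOX replicate 1 or 2) and 11 did not pass. 1 higher and 5 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0251 (0.319 with an estimated correlation). The calls of Etv4 (53.5 ± 10.6 against 842 ± 80) and Ier3 did not hold within the second wave alone, with fewer samples and log2 changes near those of the full model (-4.04 in place of -4.25 and -1.40 in place of -1.37). The count fell to 916 without replicate 1 and 870 without replicate 2 of miniSOX, and was 1414 with no wave term and 919 with first-wave replicates averaged.

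**Figure D3:**
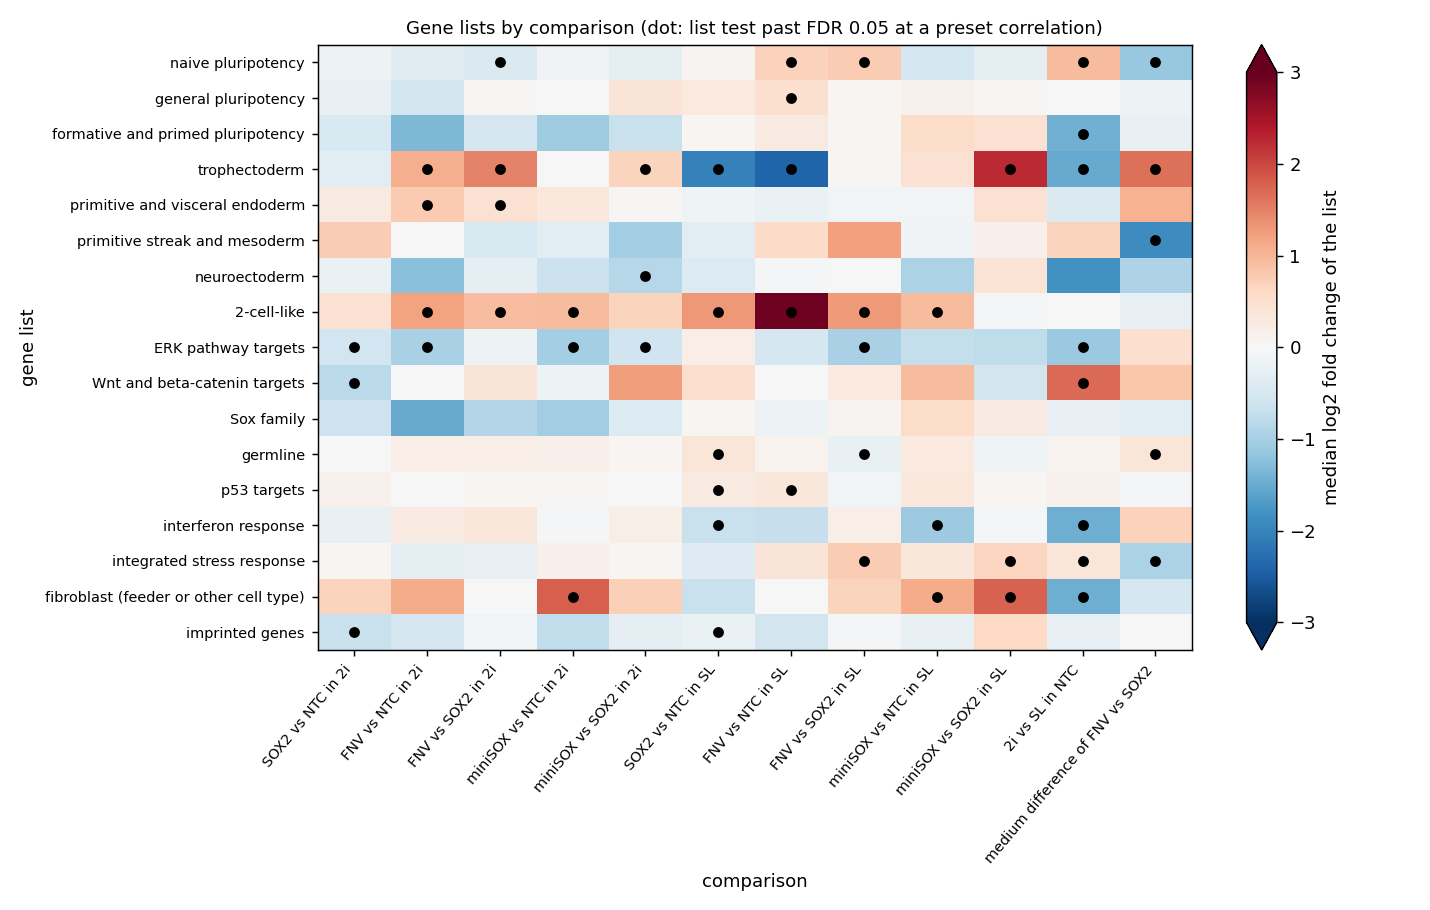
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis) as color, with a dot where the list test passed a false discovery rate of 0.05 at the preset correlation of 0.01. The trophectoderm list has a median of 1.49 for FNV against SOX2 in 2i, -2.04 for SOX2 against NTC in SL and 2.23 for miniSOX against SOX2 in SL.

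In SL, SOX2-rescued cells had lower trophectoderm genes than NTC: Krt7 was 23.5 ± 10.6 against 499 ± 91.9 (SD, n = 2 in both), Wnt7b 5.5 ± 3.54 against 171 ± 38.9, Lgals3 23.5 ± 6.36 against 235 ± 65.1 and the transcription factor Tfap2c 258 ± 39.6 against 678 ± 20.5. The imprinted genes Plagl1 (67.5 ± 2.12 against 537 ± 91.9) and Peg3 (1376 ± 55.9 against 4859 ± 272) were lower, and the germline gene Mael (383 ± 48.8 against 141 ± 5.66) was higher. Cntn3, a neural adhesion gene, was listed at 0 in both SOX2 libraries and at 382 and 411 in NTC. Among trophectoderm genes Eomes went the other way, at 112 and 109 in SOX2 and 22 and 32 in NTC libraries. Cdx2 lay between 0 and 2 in all SL libraries. In the trophectoderm list, 2 of 25 measured members rose, 13 fell and 10 did not pass. 2 higher and 15 lower passed when adjusted over the list alone, and the list test gave adjusted p = 5.77e-07 (0.174 with an estimated correlation). The interferon list, with Oasl2 at 15.5 ± 2.12 against 54.5 ± 0.707 (not passing with no wave term, at the same log2 change), went lower: 0 were higher and 2 were lower (1 without NTC replicate 1 or 2), while 12 of 14 did not pass. These genes as a list had adjusted p = 0.0287 (0.319 with an estimated correlation), and 0 higher and 2 lower passed when adjusted over the list alone. Its member Rtp4 lost its call without NTC replicate 1 or 2 or SOX2 replicate 2 and with no wave term. Without SOX2 replicate 1, the log2 change went from -4.82 to -4.23 for Wnt7b and from -4.77 to -6.06 for Rtp4, and without SOX2 replicate 2 from -4.82 to -5.40 for Wnt7b and from -4.77 to -3.48 for Rtp4. The imprinted list's 16 measured members divided into 0 higher, 5 lower (3 without NTC replicate 2 or SOX2 replicate 2) and 11 not passing. By its list test, at adjusted p = 0.027 (0.269 with an estimated correlation) the list passed, and 0 higher and 5 lower passed when adjusted over the list alone. Toward higher values went the 2-cell-like list, where 4 were higher (1 without NTC replicate 1, 2 without NTC replicate 2 or SOX2 replicate 1 or 2) and 0 were lower, while 15 of 19 did not pass. The list test had adjusted p = 0.000464 (0.443 with an estimated correlation), and 8 higher and 0 lower passed when adjusted over the list alone. In the germline list, 3 were higher (1 without NTC replicate 2 or SOX2 replicate 1) and 0 were lower, while 15 of 18 did not pass. For the list there was adjusted p = 0.0188 (0.455 with an estimated correlation), and 8 higher and 0 lower passed when adjusted over the list alone. Of p53 targets, 3 were higher (0 without NTC replicate 2 or SOX2 replicate 2, 1 without NTC replicate 1 or SOX2 replicate 1) and 0 were lower, while 14 of 17 did not pass. As a list it had adjusted p = 0.00506 (0.319 with an estimated correlation), and 3 higher and 0 lower passed when adjusted over the list alone. With each of the 4 libraries left out in turn, Mdm2 passed only without NTC replicate 1 and Sesn2 not at all, and both lost the call with no wave term. In total 2464 genes changed, 1209 higher and 1255 lower, 1042 of them by at least 2-fold. Each library weighed on this count, which was 1199 and 1297 without NTC replicates 1 and 2, and 1473 and 1422 without SOX2 replicates 1 and 2. All 4 libraries are of the first wave, and 4546 genes changed in a fit of that wave alone, 1157 in one with no wave term and 186 with first-wave replicates averaged, which leaves 1 library per arm and takes the spread from other groups.

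FNV cells in SL had higher naive pluripotency genes than NTC. Klf4 was 3801 ± 406 against 318 ± 0.707 (SD, n = 2 in both), Nanog 19100 ± 848 against 8025 ± 0 and Jam2 1558 ± 28.3 against 323 ± 0.707. The 2-cell-like gene Zscan4f was 738 ± 4.24 against 96.5 ± 7.78, a member of a family of near-identical copies, and the p53 targets Perp, Sesn1 and Cdkn1a were 488 ± 36.1 against 129 ± 1.41, 612 ± 26.9 against 328 ± 4.24 and 1375 ± 75.7 against 733 ± 9.9. Trophectoderm genes were lower, among them Krt7 (42 ± 2.83 against 499 ± 91.9), Krt19 (52 ± 8.49 against 1641 ± 84.1), Fgfr2 (32.5 ± 4.95 against 483 ± 2.83) and the placental gene Plac1 (22.5 ± 2.12 against 142 ± 8.49). Eomes went the other way, at 150 and 83 in FNV and 22 and 32 in NTC libraries. The largest changes included Cd74, the invariant chain of antigen presentation (log2 change 7.88 ± 0.56 (SE), adjusted p = 3e-07), and Sox21, a relative of Sox2, which fell to 4 in both libraries from 1597 ± 199.

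Between FNV and NTC cells in SL, 4931 genes changed, 2338 higher and 2593 lower, 2239 of them by at least 2-fold. In the naive list, 9 were higher (5 without NTC replicate 1 or FNV replicate 2) and 1 was lower, while 8 of 18 did not pass. Tested together they had adjusted p = 0.0047 (0.407 with an estimated correlation), and 10 higher and 1 lower passed when adjusted over the list alone. The general pluripotency list, in which the threonine dehydrogenase Tdh was 2262 ± 61.5 against 1169 ± 82.7, also rose: 6 were higher (3 without NTC replicate 1) and 0 were lower, while 14 of 20 did not pass. The members together had adjusted p = 0.0363 (0.44 with an estimated correlation), and 6 higher and 0 lower passed when adjusted over the list alone. For trophectoderm, 3 of 25 measured members rose, 11 fell and 11 did not pass. 4 higher and 12 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.00299 (0.243 with an estimated correlation). The 2-cell-like list's 19 measured members divided into 14 higher (8 without FNV replicate 2), 0 lower and 5 not passing. With an adjusted p = 5.16e-07 (0.269 with an estimated correlation) the list passed, and 15 higher and 0 lower passed when adjusted over the list alone. In the p53 list, 4 were higher and 0 were lower, while 13 of 17 did not pass. Camera gave adjusted p = 0.0255 (0.443 with an estimated correlation), and 4 higher and 0 lower passed when adjusted over the list alone. Without NTC replicate 1 the count was 3033, without FNV replicate 2 it was 3121, with no wave term 3210, and with replicates averaged (1 library per arm) 1027.

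Against SOX2 cells in SL, FNV cells had higher Nanog (19100 ± 848 against 5365 ± 296; SD, n = 2 in both), Klf4 (3801 ± 406 against 767 ± 240.4) and Tbx3 (2210 ± 120.2 against 1199 ± 165), while Nr0b1 was 18 ± 4.24 against 657 ± 56.6. Amino acid stress genes were higher, with the cystathionine lyase Cth at 1968 ± 463 against 522 ± 38.9 and the mitochondrial carboxykinase Pck2 at 790 ± 58 against 97.5 ± 17.7. ERK targets were lower for Ier3 (21 ± 1.41 against 174 ± 11.3), Spred1 (581 ± 53 against 1136 ± 23.3) and the immediate early factor Egr1 (15 ± 1.41 against 303 ± 189), and higher for Ccnd1 (1319.5 ± 30.4 against 564 ± 46). Egr1 was 18 and 24 in NTC cells in SL, near FNV, and 436 and 169 in the SOX2 libraries, which stood apart. Of germline genes, Tex19.1 (262 ± 100.4 against 1277 ± 404) and Rpl10l (725 ± 9.19 against 1354 ± 3.54) were lower and Stk31 (1329 ± 79.9 against 825 ± 0) higher. Cntn3 stood at 358 and 355 in FNV and was listed at 0 in both SOX2 libraries.

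For FNV against SOX2 in SL, 3513 genes changed, 1674 higher and 1839 lower, 1486 of them by at least 2-fold. The naive list's 18 measured members divided into 10 higher, 2 lower and 6 not passing. By its list test, at adjusted p = 0.00188 (0.337 with an estimated correlation) the list passed, and 11 higher and 3 lower passed when adjusted over the list alone. For the integrated stress response, 10 of 22 measured members rose (3 without FNV replicate 2, 5 without SOX2 replicate 2, 6 without SOX2 replicate 1), 1 fell and 11 did not pass. 11 higher and 1 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.000959 (0.506 with an estimated correlation). In the ERK target list, 2 were higher and 10 were lower (3 without FNV replicate 2, 4 without SOX2 replicate 1, 5 without SOX2 replicate 2, 6 without FNV replicate 1), while 5 of 17 did not pass. Over the list, camera gave adjusted p = 0.00352 (0.243 with an estimated correlation), and 2 higher and 12 lower passed when adjusted over the list alone. In the germline list, 2 were higher and 8 were lower, while 8 of 18 did not pass. The list test had adjusted p = 0.0466 (0.504 with an estimated correlation), and 2 higher and 8 lower passed when adjusted over the list alone. For 2-cell-like genes, with Zscan4f at 738 ± 4.24 against 186 ± 18.4, 5 of 19 measured members rose (2 without FNV replicate 2 or SOX2 replicate 2, 3 without SOX2 replicate 1), 0 fell and 14 did not pass. 5 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.00151 (0.455 with an estimated correlation). The count was 1791 without FNV replicate 2, 2280 and 2163 without SOX2 replicates 1 and 2, 1944 with no wave term, 5469 with first-wave libraries alone and 332 with replicates averaged (1 library per arm). Without SOX2 replicate 1, the log2 change went from -4.09 to -3.41 for Egr1, and without SOX2 replicate 2 from -4.09 to -4.77 for Egr1.

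MiniSOX cells in SL, against NTC, had higher mesenchymal genes, Tagln at 591 ± 11.3 against 48.5 ± 2.12 (SD, n = 2 in both), Thy1 at 104 ± 1.41 against 4.5 ± 0.707 and Col1a1 at 273 ± 73.5 against 48.5 ± 9.19. Thy1 in SL was 530 and 523 in FNV, 40 and 27 in SOX2. The interferon pathway genes Ddx58 and Stat2 were lower, at 258 ± 4.95 against 667 ± 21.9 and 284 ± 30.4 against 476 ± 24. Sox21 fell to 2.5 ± 0.707 from 1597 ± 199 and Nr0b1 to 1.5 ± 0.707 from 967 ± 12.7 (log2 change -9.25 ± 0.88 (SE), adjusted p = 9.41e-06). Cdh19 was listed at 0 in both NTC libraries and at 308 and 256 in miniSOX. For the fibroblast list, 5 of 14 measured members rose, 1 fell and 8 did not pass. 5 higher and 1 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0184 (0.243 with an estimated correlation). The interferon list's 14 measured members divided into 0 higher, 5 lower (3 without NTC replicate 1 or 2 or miniSOX replicate 1 or 2) and 9 not passing. By its list test, at adjusted p = 0.00807 (0.243 with an estimated correlation) the list passed, and 0 higher and 6 lower passed when adjusted over the list alone, but the list did not pass with no wave term. In the 2-cell-like list, with Tmem92 at 22.5 ± 6.36 against 2.5 ± 0.707, 2 were higher and 0 were lower, while 17 of 19 did not pass. The members together had adjusted p = 0.0184 (0.561 with an estimated correlation), and 2 higher and 0 lower passed when adjusted over the list alone. By the test 3221 genes changed, 1552 higher and 1669 lower, 1594 of them by at least 2-fold. In SL miniSOX and wave cannot be told apart except through the wave term estimated in 2i, and the count was 1876 without NTC replicate 1 and 1886 and 1899 without miniSOX replicates 1 and 2, 799 with first-wave replicates averaged (1 NTC library) and 6564 with only the compared groups in the model.

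Trophectoderm genes separated miniSOX from SOX2 cells in SL: Krt7 was 1175 ± 36.8 against 23.5 ± 10.6 (SD, n = 2 in both), Lgals3 788 ± 11.3 against 23.5 ± 6.36, Wnt7b 457 ± 56.6 against 5.5 ± 3.54 and Tfap2c 927 ± 144 against 258 ± 39.6. Mesenchymal Tagln (591 ± 11.3 against 32 ± 1.41), Col1a1 (273 ± 73.5 against 24 ± 1.41) and Col1a2 (184 ± 12 against 43.5 ± 4.95) were higher too. Cth (1469 ± 98.3 against 522 ± 38.9) and the stress factor Atf3 (92.5 ± 7.78 against 22 ± 5.66) rose while the asparagine synthetase Asns fell (4937 ± 50.2 against 8032 ± 335). As to the trophectoderm list, 16 were higher and 0 were lower, while 9 of 25 did not pass. Its list test had adjusted p = 2.12e-06 (0.174 with an estimated correlation), and 17 higher and 1 lower passed when adjusted over the list alone. For the fibroblast list, 5 of 14 measured members rose (3 without miniSOX replicate 1 or 2 or SOX2 replicate 2), 0 fell and 9 did not pass. 6 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0103 (0.243 with an estimated correlation). The integrated stress response list's 22 measured members divided into 7 higher (4 without miniSOX replicate 2 or SOX2 replicate 2), 2 lower and 13 not passing. With an adjusted p = 0.00763 (0.579 with an estimated correlation) the list passed, and 10 higher and 2 lower passed when adjusted over the list alone. Pck2 in that list (591 ± 38.9 against 97.5 ± 17.7) did not pass with no wave term (log2 change 2.60 in place of 4.24). By the test across all genes, 3547 genes changed, 1713 higher and 1834 lower, 1822 of them by at least 2-fold. Without miniSOX replicates 1 and 2 the counts were 2175 and 2119, without SOX2 replicate 2 the count was 2301, and with first-wave replicates averaged (1 SOX2 library) 972. Without SOX2 replicate 1, the log2 change went from 6.41 to 5.83 for Wnt7b, and without replicate 2 it moved as far the other way.

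Whether FNV differed from SOX2 to another extent in 2i than in SL was tested as an interaction (log2 change in 2i minus that in SL). Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635, plus strand) was 328 ± 75 in FNV and 64 ± 22.6 in SOX2 cells in 2i (SD, n = 4 in both), but 1 and 0 against 165 and 108 in SL (log2 change 8.95 ± 0.53 (SE), adjusted p = 1.69e-07). The epithelial adhesion gene Epcam had means of 2564 ± 591 against 576 ± 108 in 2i and 4956 ± 529.6 against 5298 ± 46 in SL (log2 change 2.24 ± 0.13 (SE), adjusted p = 1.69e-07). The secreted protease Htra1 (log2 change -4.24 ± 0.21 (SE), adjusted p = 1.91e-08) and the water channel Aqp3 (log2 change -3.90 ± 0.25 (SE), adjusted p = 3.93e-07) went the other way. Htra1 was 800 ± 190.3 against 832 ± 154 in 2i and 1110 ± 136 against 61.5 ± 16.3 in SL (n = 2 in both), and Aqp3 5419 ± 1609 against 3574 ± 906 and 698 ± 187 against 30 ± 4.24. The remaining interaction genes with the smallest adjusted p, Kctd12b and Cntn3, rest on groups listed at 0.

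Over all genes, 3416 genes changed, 1760 higher and 1656 lower, 1849 of them by at least 2-fold. The naive list went lower in 2i relative to SL: 2 were higher and 12 were lower, while 4 of 18 did not pass. In the list test they had adjusted p = 3.02e-05 (0.243 with an estimated correlation), and 2 higher and 12 lower passed when adjusted over the list alone. For trophectoderm, 11 of 25 measured members rose, 2 fell and 12 did not pass. 14 higher and 2 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0184 (0.319 with an estimated correlation). The primitive and visceral endoderm list did not pass: 7 were higher and 2 were lower, while 12 of 21 did not pass. Over the list, camera gave adjusted p = 0.056 (0.243 with an estimated correlation), and 7 higher and 2 lower passed when adjusted over the list alone. The primitive streak and mesoderm list's 6 measured members divided into 0 higher, 3 lower (1 without FNV replicate 2 in 2i or SOX2 replicate 1 or 2 in 2i or FNV replicate 1 or 2 in SL or SOX2 replicate 1 in SL) and 3 not passing. At an adjusted p = 0.0154 (0.269 with an estimated correlation) the list passed, and 0 higher and 4 lower passed when adjusted over the list alone. In the germline list, 9 were higher and 1 was lower, while 8 of 18 did not pass. For the list there was adjusted p = 0.00428 (0.407 with an estimated correlation), and 9 higher and 1 lower passed when adjusted over the list alone. For the integrated stress response, 1 of 22 measured members rose, 9 fell (5 without SOX2 replicate 1 in SL) and 12 did not pass. 1 higher and 12 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.000402 (0.498 with an estimated correlation). Without FNV replicate 2 in SL the count was 2096, with no wave term 1799, with first-wave libraries alone 5601, and with first-wave replicates averaged (1 library per arm in SL) 328.

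**Figure D4:**
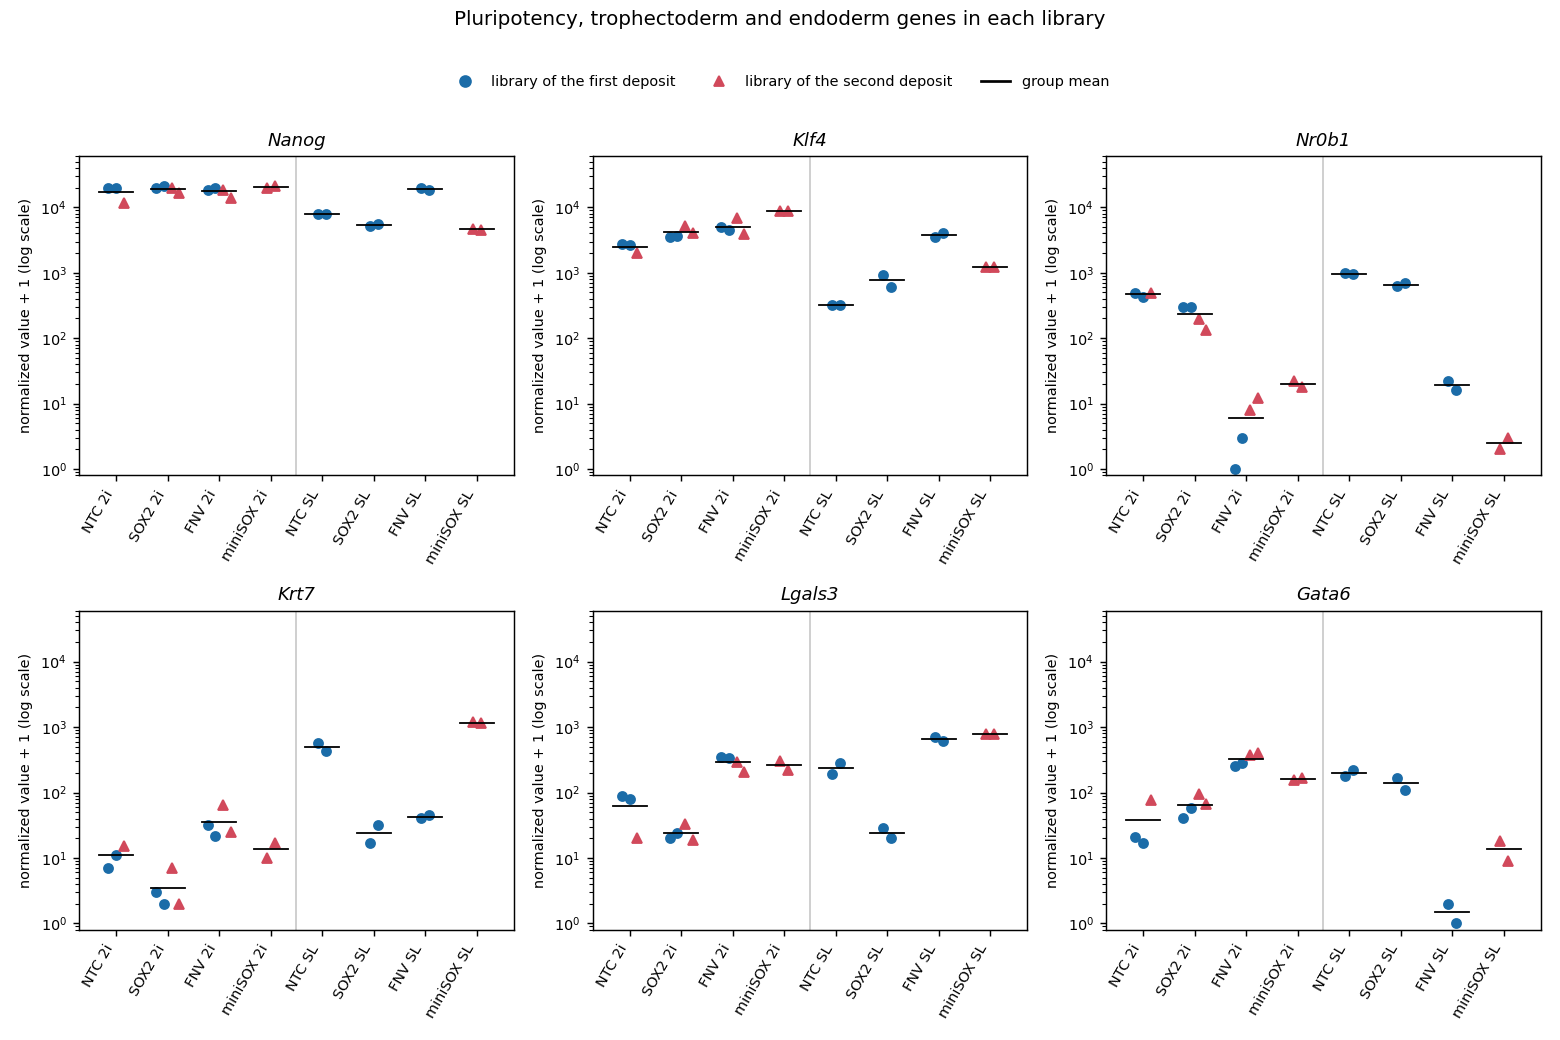
Normalized values plus 1 on a log axis for Nanog, Klf4, Nr0b1, Krt7, Lgals3 and Gata6, with 1 point per library by group, the wave as color and shape, and a line at each group mean. Nanog was 19100 ± 848 in FNV and 4629 ± 147 in miniSOX cells in SL, and Krt7 was 1175 ± 36.8 in miniSOX and 23.5 ± 10.6 in SOX2 cells in SL.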

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

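Chosen only after the result was seen were the test of the trophectoderm list against the endoderm list and the count of splits that keep the waves. The other tests in this part were set beforehand.

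A library's gap to the others of its group was large for the range of that group in 9 of 72 gene and group pairs tested. Chance gives about 1 in 20 groups where all 4 libraries vary alike, which these do not: among genes between 500 and 1500, the SD of the log2 difference was 0.109 between replicates 1 and 2 and 0.27 between p21 and p31 in SOX2 cells, and 0.129 and 0.406 in FNV cells. In SOX2 cells in 2i, the p21 library had Sp5 at 42 (others 7 to 9) and H19 at 1525 (others 40 to 142), and the p31 library had Fabp4 at 86 (others 34 to 41). In FNV cells in 2i, the p21 library had Sp110 at 154 (others 72 to 74) and H19 at 19697 (others 5573 to 7059). The p31 library of FNV had Etv4 at 129 (others 15 to 22), Cdx2 at 452 (others 217 to 245) and Plat at 168 (others 301 to 325). For Ier3, the p21 library of FNV had 26 and the other 3 had 23, a gap that is large only because rounded values tie. All 9 values came from second-wave libraries.

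Of 54 differences between media tested for named genes, 34 passed, each given here as the log2 change in 2i minus that in SL. Of these genes Gata6, Epcam, Htra1, Aqp3, Kctd12b and Cntn3 were named for the smallest adjusted p of this same difference for FNV against SOX2, so that choice fixed their passing. For FNV against SOX2, genes higher in 2i relative to SL included, of the trophectoderm and endoderm lists (the endoderm list did not pass), Krt18 (4.57 ± 0.57 (SE), adjusted p = 0.000106), Krt8 (3.85), Cdx2 (6.06), Wnt7b (3.32), Gata6 (8.95), Dab2 (3.32) and Lrp2 (2.77). Epcam (2.24), H19 (6.77), Dppa3 (1.22), Tex19.1 (2.53), Egr1 (4.24) and Ier3 (2.80) went the same way. In 2i, Egr1 was 1 to 3 in both lines and Ier3 23 to 26 against 25 to 30. Cdx2 was 0 or 1 in SL. Naive genes were lower in 2i relative to SL, with Nanog (-1.97 ± 0.19 (SE), adjusted p = 1.21e-05), Klf4 (-2.06), Tbx3 (-1.19), Prdm14 (-1.30) and Tcl1 (-4.83). So were the stress genes Cth (-2.27), Psat1 (-0.76) and Pck2 (-3.04), as well as Ccnd1 (-1.45), Stk31 (-0.43), Htra1 (-4.24), Aqp3 (-3.90), Ntn1 (-2.16), Notch4 (-2.58) and Sox17 itself (-2.68, not passing at a pseudocount of 0.1). Kctd12b (-8.99) and Cntn3 (-8.58) rest on groups listed at 0, so their fitted values give no fold.

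For SOX2 against NTC, Sox17 differed between media (2.09) at values of 6 or below. For FNV against NTC, Sox2 (-1.65) and Tmem92 (-2.01) differed, and for miniSOX against SOX2, Wnt7b (-2.93). Over all genes, 3416 differed between media for FNV against SOX2. For the counts in 2i with at least 3 libraries per group, 1 of the 35 splits of the same 7 libraries gave as many changed genes as SOX2 against NTC, the real split alone, with 4718 genes against 2367 for the highest other. FNV against NTC gave the same share, 1 of 35, with 6529 against 4512. Of 8 libraries split 4 and 4, FNV against SOX2 was again 1 of 35, with 4150 against 2237. A random division can be excluded for these 3 counts only if all libraries can be exchanged. The splits that keep the waves number 18 for each count, too few for a share under 0.05, and the highest other among them was again 2367, 4512 and 2237.

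The naive list was lower in FNV than in SOX2 cells in 2i (median -0.44) and higher in SL (median 0.75), neither passing with an estimated correlation (adjusted p = 0.443 and 0.337). A difference between waves is argued against, since within the first wave the median difference between media was -1.32, with 14 members passing the threshold and lower. A dose effect of the introduced factor stays open: Sox17 in FNV cells in SL differed 2.22 times between libraries while the list differed by a median of 0.04, and 2 libraries are too few to decide. A response of FNV cells to the medium itself is a hypothesis that remains untested, because factor level and medium cannot be told apart here.

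In SL the trophectoderm list was lower in SOX2 than in NTC cells (median -2.04) and higher in miniSOX than in SOX2 cells (median 2.23), neither passing with an estimated correlation (adjusted p = 0.174 for both). The waves do not enter the first part, since all 4 libraries are of the first wave. For the second, a wave effect as in 2i is argued against, since the wave term had a median of 0.24 over the list (SD 1.28) and the median change was 2.49 with no such term, but a wave effect particular to SL cannot be told apart from miniSOX. A larger share of cells that are not stem cells in NTC stays open: the endoderm list had a median of -0.13 in SOX2 against NTC, with 4 members lower (such as Plat, -2.06) and Hnf4a higher (2.85). An effect of the rescue factor stays open and untested: Sox2 did not pass between SOX2 and NTC in SL (adjusted p = 0.238), and of the 2 lines with low Sox2, FNV (49 and 33) had a lower list than NTC (median -2.40) while for miniSOX (48 and 55) the list did not pass (median 0.46, adjusted p = 0.292).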

How the results depend on the processing

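Chosen after seeing the data were the tests with a pseudocount of 10, a mean of at least 50, the column prefix, the median log ratio or without step genes. So were the tests of single genes by wave, with the block or without a library, of list members without a library, and every test of the 3 comparisons of miniSOX with FNV or between media. All 15 counts of changed genes stayed within 1.5 times of the value given under pseudocounts of 0.1 and 10, the filter at 50, the prefix term, centring (library shifts of -0.013 to 0.037), repeated normalization, the replicate block, and without step genes. With the replicate block the counts ran 4463, 6299, 3906, 4273, 2260, 2230, 4682, 3291, 2986, 3267, 3835, 3191 in the order of the report's design (SOX2 and FNV against NTC, FNV against SOX2, miniSOX against NTC and SOX2, in 2i and then in SL, then media in NTC and between media), and it changed no call of a named gene. The numbers do not pair the samples: over 28 pairs of groups the correlations of deviations ran from -0.092 to 0.086, 0 of them over 0.1. The p21 minus p31 deviations of SOX2 and FNV cells in 2i correlated at 0.109, and the prefix as a term is among the settings above. Other settings moved counts by more than 1.5 times, and the cause was not tested. With no wave term they were 2947 (SOX2 against NTC in 2i), 2695 (FNV against SOX2 in 2i), 1414 (miniSOX against SOX2 in 2i), 1157 (SOX2 against NTC in SL), 3210 (FNV against NTC in SL), 1944 (FNV against SOX2 in SL), 2680 (2i against SL in NTC), 1799 (FNV and SOX2 between media), 276 (miniSOX against FNV in 2i). First-wave libraries alone gave 4546 (SOX2 against NTC in SL), 5469 (FNV against SOX2 in SL), 5601 (FNV and SOX2 between media). Second-wave libraries alone, fewer samples, gave 1529 (SOX2 against NTC in 2i), 2911 (FNV against NTC in 2i), 837 (FNV against SOX2 in 2i), 2837 (miniSOX against NTC in 2i), 1079 (miniSOX against SOX2 in 2i), 107 (miniSOX against FNV in 2i). First-wave replicates averaged, which leaves 1 library of NTC, SOX2 and FNV in SL that is assumed to vary like the other groups, gave 1694 (SOX2 against NTC in 2i), 3985 (FNV against NTC in 2i), 1545 (FNV against SOX2 in 2i), 2772 (miniSOX against NTC in 2i), 919 (miniSOX against SOX2 in 2i), 186 (SOX2 against NTC in SL), 1027 (FNV against NTC in SL), 332 (FNV against SOX2 in SL), 799 (miniSOX against NTC in SL), 972 (miniSOX against SOX2 in SL), 789 (2i against SL in NTC), 328 (FNV and SOX2 between media), 72 (miniSOX against FNV in 2i), 394 (miniSOX against FNV in SL). Only the compared groups in the model gave 6947 (miniSOX against NTC in 2i), 6564 (miniSOX against NTC in SL), 91 (miniSOX against FNV in 2i), 4845 (miniSOX against FNV in SL). Leaving out 1 library at a time, a lone remaining library being assumed to vary like the other groups, gave ranges of 2712 to 4185 (miniSOX against NTC in 2i), 870 to 2234 (miniSOX against SOX2 in 2i), 1199 to 1473 (SOX2 against NTC in SL), 3033 to 3592 (FNV against NTC in SL), 1791 to 2561 (FNV against SOX2 in SL), 1876 to 2223 (miniSOX against NTC in SL), 2119 to 2745 (miniSOX against SOX2 in SL), 2106 to 4713 (2i against SL in NTC), 2096 to 4510 (FNV and SOX2 between media), 127 to 2994 (miniSOX against FNV in 2i), 1240 to 1696 (miniSOX against FNV in SL). Of the 52 list tests that passed, 0 held with an estimated correlation, and 60 passed with no wave term, 3 of the 52 losing the call there (neuroectoderm for miniSOX against SOX2 in 2i, interferon for miniSOX against NTC in SL, and integrated stress response between media in NTC). Of 206 named gene results, 2013 of 2053 alternative values kept direction and call, 40 lost the call and 0 reversed, while 14 of 206 lost it without at least 1 library. Of the 52 list tests, 29 had a count of changed members that moved by more than 1.5 times without at least 1 library, given beside each count. The tests and size factors planned for count tables were not run, since the values are not counts, and first-wave replicates were averaged where sums had been planned. The setting with no filter was not run either, because the filter left out 0 genes. Read depth, which is unknown, limits what a value of 0 can show.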

Other observations

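The comparisons of miniSOX with FNV cells and of miniSOX cells between media, the genes named for them, and the tests of GC content, of few reads and of step genes that follow the groups were chosen only after the values were seen. In SL, miniSOX cells had lower naive genes than FNV cells, with Nanog at 4629 ± 147 against 19100 ± 848 (SD, n = 2 in both), Klf4 at 1210 ± 3.54 against 3801 ± 406, Tbx3 at 746 ± 28.3 against 2210 ± 120.2 and Klf2 at 802 ± 81.3 against 2468 ± 738. Trophectoderm genes were higher: Krt7 was 1175 ± 36.8 against 42 ± 2.83, Plac1 270 ± 7.07 against 22.5 ± 2.12 and the homeobox genes Rhox6 and Rhox9 974 ± 40.3 against 40 ± 2.83 and 671 ± 5.66 against 63.5 ± 9.19. Of the genes looked at in this comparison, the matrix protein gene Tinagl1 had the smallest adjusted p (694 ± 26.9 against 8 in both FNV libraries; log2 change 6.58 ± 0.28 (SE), adjusted p = 4.46e-09). In total 2499 genes changed, 1216 higher and 1283 lower. In the naive list, 0 were higher and 11 were lower, while 7 of 18 did not pass. For the list there was adjusted p = 1.21e-08 (0.102 with an estimated correlation), and 0 higher and 13 lower passed when adjusted over the list alone. Of trophectoderm genes, 15 of 25 measured members rose (9 without miniSOX replicate 1), 0 fell and 10 did not pass. 17 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 4.56e-07 (0.0671 with an estimated correlation). The primitive and visceral endoderm list's 21 measured members divided into 8 higher (2 without FNV replicate 2 or miniSOX replicate 1, 3 without miniSOX replicate 2, 5 without FNV replicate 1), 1 lower and 12 not passing. With an adjusted p = 0.0395 (0.111 with an estimated correlation) the list passed, and 8 higher and 1 lower passed when adjusted over the list alone. For 2-cell-like genes, 0 were higher and 4 were lower (1 without FNV replicate 1 or 2 or miniSOX replicate 1 or 2), while 15 of 19 did not pass. The members together had adjusted p = 0.000151 (0.436 with an estimated correlation), and 0 higher and 7 lower passed when adjusted over the list alone. Of germline genes, 5 were higher (1 without miniSOX replicate 1 or 2, 2 without FNV replicate 1, 3 without FNV replicate 2) and 0 were lower, while 13 of 18 did not pass. Its list test had adjusted p = 0.0482 (0.572 with an estimated correlation), and 7 higher and 0 lower passed when adjusted over the list alone. The wave cannot be told apart from miniSOX in SL, and the count was 1470 without FNV replicate 1 and 1240 and 1324 without miniSOX replicates 1 and 2, 394 with first-wave replicates averaged (1 FNV library) and 4845 with only the compared groups in the model.

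In 2i, Krt8 (1192 ± 103 against 3176 ± 549.5; SD, n = 2 and 4), Krt18 (727 ± 15.6 against 2212 ± 749), Gata3 (22.5 ± 2.12 against 114 ± 37.7) and Dab2 (2444 ± 84.2 against 4505 ± 552) were lower in miniSOX than in FNV cells, and the TGF-beta family gene Nodal (707 ± 7.07 against 274 ± 14.9) was higher. Without miniSOX replicate 1 none of these 5 calls held, and without replicate 2 only that of Gata3, although the log2 changes moved by less than 1.5 times. Between miniSOX and FNV cells in 2i 1260 genes changed, 627 higher and 633 lower in miniSOX, against 107 within the second wave. Whether the lines differ less in 2i than in SL was not tested. Of trophectoderm genes, 1 was higher and 5 were lower (0 without miniSOX replicate 1, 1 without miniSOX replicate 2, 3 without FNV replicate 1 or 2), while 19 of 25 did not pass. The set gave adjusted p = 0.00912 (0.219 with an estimated correlation), and 1 higher and 8 lower passed when adjusted over the list alone. The integrated stress response list passed toward higher values (median log2 change 0.36) although 0 of 22 measured members rose (6 without FNV p21), 0 fell and 22 did not pass. 0 higher and 0 lower passed when adjusted over the list alone, and the list test gave adjusted p = 0.0395 (0.669 with an estimated correlation). The count was 140 and 127 without miniSOX replicates 1 and 2, 835 without FNV replicate 1, 2994 without the FNV p21 library, 276 with no wave term, 72 with first-wave replicates averaged and 91 with only the compared groups in the model.

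Between media, 5495 genes changed in miniSOX cells, 2793 higher and 2702 lower in 2i. Nanog (20440 ± 1053 against 4629 ± 147; SD, n = 2 in both), Tbx3 (3039 ± 169.7 against 746 ± 28.3) and Prdm14 (325 ± 3.54 against 62 ± 5.66) were higher in 2i, while Pou3f1 (1.5 ± 0.707 against 518 ± 33.9) and Otx2 (56 ± 2.83 against 311 ± 29.7) were lower. The formative and primed list went down in 2i: 0 were higher and 15 were lower, while 2 of 17 did not pass. In the list test they had adjusted p = 1.21e-08 (0.0011 with an estimated correlation), and 0 higher and 16 lower passed when adjusted over the list alone. This list test alone, of the 3 added comparisons, held with the estimated correlation. In the naive list, 12 were higher and 0 were lower, while 6 of 18 did not pass. These genes as a list had adjusted p = 4.56e-07 (0.111 with an estimated correlation), and 12 higher and 0 lower passed when adjusted over the list alone. The trophectoderm list's 25 measured members divided into 3 higher, 16 lower and 6 not passing. At an adjusted p = 4.44e-05 (0.102 with an estimated correlation) the list passed, and 3 higher and 17 lower passed when adjusted over the list alone. For ERK targets, 1 was higher and 11 were lower, while 5 of 17 did not pass. The list test had adjusted p = 0.000151 (0.102 with an estimated correlation), and 1 higher and 11 lower passed when adjusted over the list alone. For Wnt targets, 7 were higher and 2 were lower, while 6 of 15 did not pass. For the list there was adjusted p = 0.0143 (0.209 with an estimated correlation), and 7 higher and 2 lower passed when adjusted over the list alone. For the fibroblast list, 0 were higher and 5 were lower, while 9 of 14 did not pass. As a list it had adjusted p = 0.0415 (0.219 with an estimated correlation), and 0 higher and 5 lower passed when adjusted over the list alone. For imprinted genes, 2 were higher and 11 were lower, while 3 of 16 did not pass. Tested together they had adjusted p = 0.00496 (0.111 with an estimated correlation), and 2 higher and 12 lower passed when adjusted over the list alone.

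The 691 step genes, listed at 0 in some libraries and at 20 or more in all others, include 167 olfactory and vomeronasal receptor genes. Few reads per gene as the whole cause is argued against, since 0.867% of genes with a 0 above 50% GC were step genes and 73.2% of those below 42% GC. Switching of genes between groups is argued against as the cause of the whole set, since 35.9% of gene and group pairs held both 0 and other values, against 42.2% after the libraries were shuffled. For a part of the set it stays open: 269 step genes, Kctd12b, Cntn3 and Cdh19 among them, were at 0 in every library of a group and above 0 in every library of another, against a mean of 187 and at most 231 in 200 shuffles. A scaling by GC content within the authors' normalization may have turned small values of genes low in GC into larger ones: across the 2142 genes with a 0, GC content and the smallest value above 0 had a Spearman rho of -0.72 (genes are not independent replicates). Step genes made up between 8.25% and 23.8% of the genes changed at least 8-fold, depending on the comparison.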
